A study of Mus musculus with 16 samples.

How the data were processed

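The study measured gene expression in CD11b-positive cells from spleen or bone marrow of wild-type, STAT4 knockout, STAT6 knockout and HDC knockout mice on a control or a high-fat diet, with 16 one-colour Cy3 arrays of 44397 spots and 1 array per combination. Per the labels, each RNA is a pool of 5 mice. The deposited files give intensity values: the authors ran Agilent Feature Extraction 11.0.1.1 with its one-colour protocol, which writes a background-subtracted, spatially corrected intensity for each spot, with no scaling between arrays. Groups were taken from the labels alone. The 4 slides carry wild-type and STAT4 spleen, STAT6 and HDC spleen, wild-type and STAT4 marrow, and STAT6 and HDC marrow, so that both diets of a genotype lie on the same slide while tissues, and STAT6 and HDC against wild type, lie on different slides. Whether spleen and marrow of a group came from the same mice is not given in the sources used here.

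Probes were named through the RefSeq accessions of the files and a table of mouse gene symbols; 27234 of 39429 probes (69.1%) matched, giving 20659 symbols, and unmatched probes were tested under their own identifiers. The probe design used an older genome build than the symbol table, so no coordinates are given, and chromosome and gene order were taken from the symbol table. A total of 305 probes marked as non-uniform or outlying on some array were left out, which includes the only Hdc probe, reported from the 15 arrays where its spot was usable. Signals were put on the log2 scale, and the 75th percentile of each array was subtracted. Each gene was read from its brightest probe and kept if well above background on at least 2 arrays. The share of probes above background and the median signal describe the depth of each array; no spot was saturated.

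The main fit used limma 3.58.1 in R 4.3.3 (files read with version 1.17.8 of data.table), with a mean for each genotype in each tissue and a diet term in each tissue (6 residual degrees of freedom), empirical Bayes variances, two-sided tests and Benjamini-Hochberg adjustment over all 28469 features, with calls at an adjusted p under 0.05. Diet by genotype was tested in a model with all pairwise terms (3 residual degrees of freedom). Targeted genes were compared with all other arrays by exact two-sided permutation. Of cell-type and pathway lists, 37 were written before the files were seen and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A bound ("at least N-fold") is given where a gene was not above background on any array of 1 arm. Named genes follow a fixed rule: up to 10 on each side, called by limma with the same direction in every pair, ranked by change, and where fewer than 3 qualify, the 5 smallest p on each side. Itgam, Stat4 and Stat6 were looked up in each comparison. Figures were drawn with matplotlib 3.10.9 from the same tables.

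These comparisons, lists, thresholds and the alternatives of scaling, filter, probe choice, prior, model, block and array left out were chosen before the data were examined. The alternative with background correction was planned on the mean spot signal, which the files do not hold, so normexp (offset 50) used the median spot and background signals. Fits with only wild-type and STAT6 knockout arrays, with the Y-linked signal as a covariate, without the 2 arrays nearer the other tissue, without the control-diet arrays labelled STAT4 knockout, and with genotype terms shared by both tissues were chosen after seeing the data. The tests were also run on simulated data, made of each gene's mean plus independent normal noise with the residual SDs shuffled over genes. Such data hold no correlation between genes, no outlying array and no slide or sex difference. Changes of 2 log2 were added, and 83.6% were recovered for tissue, 50.8% for diet in spleen and 71.6% for HDC. False calls among 28269 unchanged features numbered 9, 3 and 5 in that order. Diet by HDC had 0% recovered and 0 false calls.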

Results

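The Cy3 signal of mouse gene probes was read on 16 arrays, with 1 array for each combination of 4 genotypes, 2 tissues and 2 diets. The genotypes were wild type and mice labelled as lacking the transcription factors STAT4 or STAT6 or the histamine-forming enzyme HDC. CD11b-positive cells came from the spleen or the bone marrow of mice on a control diet or on a high-fat diet for 3 months, and each array holds RNA pooled from 5 mice. No combination was measured on a second array, so the number of arrays limits every estimate below, and no comparison rests on repeats of the same pool. The median spot signal ran from 74.0 (STAT6 knockout marrow, high-fat diet) to 183.9 (wild-type and STAT6 knockout spleen, high-fat diet), and 59.7% to 85.3% of probes were well above background. The 4 marrow arrays of STAT6 and HDC knockout mice, which share a slide, had the lowest shares (59.7% to 68.6%), against 70.2% or more on every other array. Tests covered 28469 features, of which 18664 carry a gene symbol.

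Do the arrays carry the gene losses their labels state? Hdc signal was low on all 4 arrays labelled HDC knockout (mean 1.36, SD 0.39, n = 4, in log2 over the 75th percentile of the array) and high on the other arrays with a usable spot (4.96, SD 0.62, n = 11). The difference from wild type was -3.72 (SE 0.30; 13.2-fold), with an exact two-sided permutation p of 0.000733 against all other arrays. Stat6 was lower on the arrays labelled STAT6 knockout (2.62, SD 0.21, n = 4) than on the others (3.31, SD 0.60, n = 12; exact two-sided permutation p 0.044), and its other probes gave exact p of 0.0011 and 0.11. Stat4 was not low on the arrays labelled STAT4 knockout. It read 3.35 in spleen and 2.60 in marrow on the high-fat arrays labelled STAT4 knockout, above the highest value of the 12 other arrays (1.15), and 0.42 and 0.27 on the control-diet arrays, inside the range of the others (exact two-sided permutation p 0.0225 for a higher mean, 1.66 against 0.27). On those control-diet arrays labelled STAT4 knockout, the brightest Stat6 probe read 2.44 in spleen and 2.19 in marrow (2.39 to 2.90 on the arrays labelled STAT6 knockout). The Stat6 probe with the lowest p read -3.71 and -4.28 there, below every wild-type array, but the spleen value lay above all 4 arrays labelled STAT6 knockout (-5.29 to -4.10). The part of each gene that was deleted is not in the labels, and a probe outside that part cannot check a label. The Stat4 signal thus neither bears out nor refutes the STAT4 label. Each direction given below for "the arrays labelled STAT4 knockout" rests on that label alone.

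**Figure D1:**
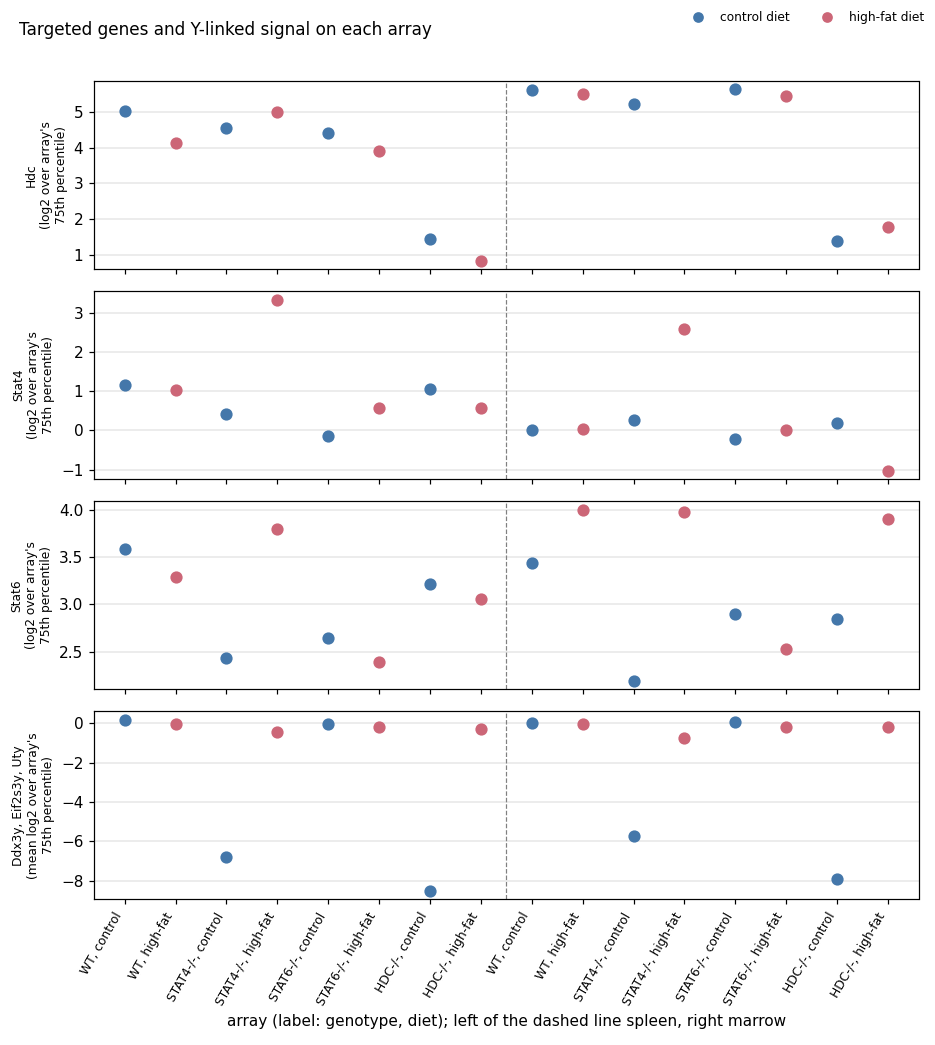
Signal of Hdc, Stat4, Stat6 and the mean of 3 Y-linked genes on each of the 16 arrays (log2 over the array's 75th percentile; 1 point per array, 1 array per group). Hdc lies at 0.83 to 1.77 on the 4 arrays labelled HDC knockout, Stat4 is highest on the high-fat arrays labelled STAT4 knockout (3.35 and 2.60), and Y-linked signal is lowest on 4 control-diet arrays (-8.52 to -5.72).

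All mice were labelled male, and the Y-linked genes Ddx3y, Eif2s3y and Uty had a mean signal of -0.76 to 0.18 on 12 arrays. On the other 4 arrays the mean was -6.81 and -5.72 (control-diet spleen and marrow labelled STAT4 knockout) and -8.52 and -7.94 (HDC knockout spleen and marrow, control diet). Xist, transcribed from the inactive X chromosome of females, read -4.35 to -3.06 on those 4 arrays and -9.42 to -5.58 on the others. In these genotypes the diet comparison is thus mixed with whatever sets the sex-linked signal apart, and 8 of the 16 arrays belong to them. Their comparisons with wild type are mixed with it too, since all 4 wild-type arrays had Y-linked signal (-0.04 to 0.18).

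Which genes separate CD11b-positive cells of the spleen from those of the marrow? Adam23 (log2 change 6.39, SE 0.32), the chemokine receptor gene Ccr6 (6.04, SE 0.53), Postn (5.86, SE 0.49), Gimap7 (5.63, SE 0.57), Dapl1 (5.53, SE 0.34), Anpep (5.42, SE 0.38), Gpr174 (5.21, SE 0.72), Tnfrsf25 (5.14, SE 0.57), Cr2 (5.14, SE 0.47) and Dtx1 (5.10, SE 0.50) were the genes most raised in spleen. Each had this direction in 8 of 8 pairs of arrays matched for genotype and diet (adjusted p 5.23e-05 to 0.00113). Those most raised in marrow were 4933405E24Rik (-4.39, SE 0.99), the niche chemokine gene Cxcl12 (-4.38, SE 0.69), Ccne2 (-4.13, SE 0.33), Krtap20-2 (-4.04, SE 0.24), Vpreb2 (-4.01, SE 0.59), Pip5k1b (-3.97, SE 0.32), Phldb2 (-3.54, SE 0.22), Vpreb1 (-3.44, SE 0.71), Cplx2 (-3.44, SE 0.59) and Ctsk (-3.33, SE 0.28). They too had their direction in 8 of 8 pairs (adjusted p 9.08e-05 to 0.00932). Few arrays of the lower tissue had some of these above background (2 of 8 for Adam23, Postn, Vpreb2 and Phldb2, 3 for Dapl1, 4 for Gpr174 and Tnfrsf25, 1 for Ccne2), so their size and rank depend on the floor. Itgam, which encodes CD11b, averaged 4.25 (SD 0.89, n = 8) in spleen and 5.56 (SD 0.44, n = 8) in marrow, a change of -1.30 (SE 0.29, adjusted p 0.00934, 7 of 8 pairs). With limma, 4191 features were higher in spleen and 4939 lower, and 3048 named genes were called with the same direction in all 8 pairs. The median of all features was -0.06. The 9130 calls became 5731 without wild-type marrow, control diet, and 10640 without HDC knockout marrow, control diet. Of the 9130, 4991 were at least 2-fold. With slide as a random block 8689 were called. Each slide holds a single tissue and each tissue lies on 2 slides, so slide could not be fitted as a fixed term.

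Lymphoid and antigen-presenting genes were among those higher in spleen, although the cells were selected on CD11b. In the B cell list, 14 of 16 genes were called higher and 0 lower (15 and 0 adjusted over the list alone, median 3.22, adjusted p 7.51e-10), led by Cxcr5 (4.83), Fcmr (5.05), Cr2 (5.14) and Fcer2a (3.27); with an estimated correlation the adjusted p was 0.423. Of these 16 genes, 14 were well above background on all 8 marrow arrays too, and 2 belong to another list. In the T cell list 14 of 15 were higher and 1 lower (the same over the list alone, median 2.94, adjusted p 7.51e-10, or 0.423 with an estimated correlation), among them Bcl11b (4.97), Cd5 (4.40), Tcf7 (4.02) and Cd8a (3.28). The natural killer cell list had 13 of 16 higher (13 over the list alone, median 2.52, adjusted p 1.91e-07, or 0.511 with an estimated correlation), with Klrg1 at 3.65, Tbx21 at 3.65 and Prf1 at 2.21. MHC class II presentation genes had 11 of 14 higher (11 over the list alone, median 2.98, adjusted p 1.83e-09, or 0.423 with an estimated correlation). Conventional dendritic cell genes had 13 higher and 1 lower of 16 (15 and 1 over the list alone, median 2.50, adjusted p 5e-09, or 0.423 with an estimated correlation), with Batf3 at 3.22 and Xcr1 at least 4.64-fold higher, as no marrow array had it above background. Red pulp macrophage genes had 13 higher and 1 lower of 20 (15 and 1 over the list alone, median 2.17, adjusted p 9.36e-07, or 0.511 with an estimated correlation), with Spic at 3.92, Mertk at 2.80 and C1qb at 2.53.

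On the marrow side, proliferation and granule genes stood out. In the cell cycle list 22 of 25 genes were lower in spleen (24 over the list alone, median -1.22, adjusted p 7.35e-09, or 0.513 with an estimated correlation), with Aurkb at -3.08, Cdk1 at -2.13 and Top2a at -1.41. The mature neutrophil list had 9 of 15 lower (10 over the list alone, median -0.72, adjusted p 0.000305, or 0.511 with an estimated correlation), including Mmp9 (-1.85), Mmp8 (-1.56, 7 of 8 pairs) and Fpr1 (-1.38). The primary granule list had 5 of 9 lower (6 over the list alone, median -1.59, adjusted p 0.00481, or 0.513 with an estimated correlation), with Mpo at -1.85 (7 of 8 pairs) and Elane at -1.69 (7 of 8 pairs). The secondary granule list had 6 of 10 lower (8 over the list alone, median -0.75, adjusted p 0.00361, or 0.513 with an estimated correlation). Of 37 lists, 19 were shifted by camera, 0 with an estimated correlation, and 20 by fry. Over all 8 main comparisons the counts were 150, 0 and 22, so no list call of these comparisons holds with an estimated correlation, which was not run for the settings with fewer arrays or a covariate.

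**Figure D2:**
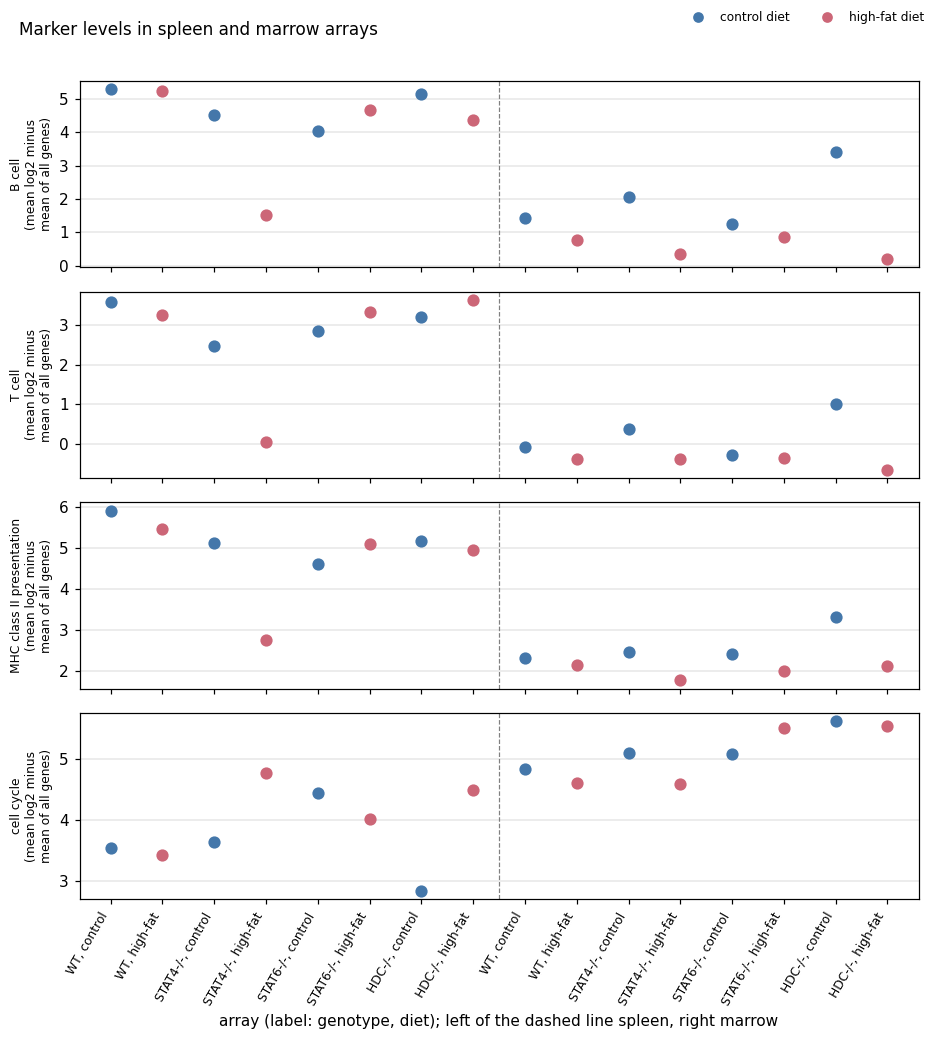
Mean level of B cell, T cell, MHC class II and cell cycle genes on each of the 16 arrays (log2, minus the mean of all tested features; 1 point per array). B cell genes lie at 4.03 to 5.29 on 7 spleen arrays but at 1.51 on the high-fat spleen array labelled STAT4 knockout, and at 3.40 on the HDC knockout marrow array, control diet, against 0.20 to 2.06 on the other marrow arrays.

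The first principal component held 42.5% of the variance and separated the tissues except for 2 arrays. The spleen array labelled STAT4 knockout, high-fat diet, correlated more with the marrow arrays (mean r 0.97) than with the other spleen arrays (0.95). HDC knockout marrow, control diet, lay closer to spleen (0.954) than to marrow (0.947). On the first of these the T cell list stood at 0.05 against 2.47 to 3.64 on the other spleen arrays. On the second the pro-B and pre-B list stood at 3.91 against -1.60 to 1.70 on the other marrow arrays. Both arrays enter the diet and knockout comparisons below.

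Did 3 months of high-fat diet change expression in either tissue? In spleen the 5 genes with the smallest p on the higher side were not above background on any control-diet array. Olfr1013 was at least 2.37-fold higher, Cntnap4 at least 2.17-fold, Phldb2 at least 1.5-fold and Ces1c at least 1.13-fold, the last 2 above background on 2 of 4 high-fat arrays each. Fam90a1a has no bound above 1 and was above background on 1. On the lower side, relative to the median of all features (0.15), were Akap7 (-2.86), Phax (-2.01), Tmem229a (-1.52), Pla1a (-1.17) and the interferon-inducible GTPase gene Iigp1 (-2.23). Each of the 10 had its direction in 4 of 4 pairs, and the SE ran from 0.23 (Pla1a) to 0.47 (Iigp1). The adjusted p was 0.456 for Akap7 and Olfr1013 and 0.771 for the other 8. In marrow, relative to a median of 0.11, the smallest p fell to Olfr281 (1.08), 5730522E02Rik (1.22), Zbtb37 (0.94), the sterol sensor gene Insig1 (1.42) and Clstn1, which no control array had above background (at least 1.24-fold). Lower were Dnase1 (-1.57, above background on 1 high-fat array), H2-Ab1 (-1.47), Mybpc2 (-1.96), Pcdhb7 (at least 1.24-fold) and Gal3st1 (no bound), the last 2 above background on no high-fat array. Each was in 4 of 4 pairs with an adjusted p of 0.69 and an SE of 0.22 (Olfr281) to 0.44 (Mybpc2). Over both tissues (median 0.13) Akap7 was at -2.09 (SE 0.27, 8 of 8 pairs, adjusted p 0.383), Pcdhb7 at -1.48, Enkur at -1.46, Adamdec1 at -2.11 and Tmem229a at -1.18. Higher were 1810010H24Rik at 0.82 (8 of 8 pairs) and Olfr1013 at 1.13 (6 of 8 pairs), and, above background on no control array, Nt5c1b (at least 1.27-fold), Fam90a1a and Ces1c (no bound; 8 of 8 pairs each), all with an adjusted p of 0.383. With limma 0 features passed in spleen (1275 at an unadjusted p under 0.05), 0 in marrow (1738), 0 over both (3628) and 0 for the difference between tissues (312), where chance gives 1423. Every other scaling, filter and model also gave 0. On simulated data, 50.8% of changes of 2 log2 in spleen and 83.6% over both tissues were recovered, but only 4.48% and 20.9% of changes of 1 log2. Smaller effects would be missed.

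By camera at the preset correlation, interferon-responsive genes were lower on the high-fat diet as a group. By fry, 0 of 37 lists were shifted in any diet comparison. In spleen, 0 of 25 genes of the type I interferon response list had a positive change (0 called, 0 over the list alone, median -1.13 relative to all features, adjusted p 9.69e-18, or 0.333 with an estimated correlation), with Oasl2 at -1.69 and Oasl1 at -1.57 (4 of 4 pairs each) and Rtp4 at -1.41 (4 of 4). The mean level of the list was 5.24 on control and 4.09 on high-fat diet in wild-type spleen, 3.56 and 3.22 in STAT6 knockout spleen, 6.17 and 2.88 in HDC knockout spleen, and 3.31 and 3.17 on the spleen arrays labelled STAT4 knockout. With only the wild-type and STAT6 knockout arrays, a setting chosen after seeing the data, the adjusted p was 2.81e-17, and the mean difference of the type I interferon response list was -0.74 against -1.23 over 4 pairs. In marrow the list's median was -0.55 (adjusted p 7.65e-05, or 0.574 with an estimated correlation). By pair its level differed there by -1.70 in HDC knockout, -0.45 in wild type, -0.21 in STAT6 knockout and 0.08 on the arrays labelled STAT4 knockout, so HDC knockout weighs most. In spleen, cell-type lists moved the same way over all pairs: conventional dendritic cell (0 called, 3 lower over the list alone, median -1.05, adjusted p 3.01e-09, or 0.147 with an estimated correlation), nonclassical monocyte (0 called, 0 over the list alone, -0.68, adjusted p 3.43e-07, or 0.147) and plasmacytoid dendritic cell (0 called, 0 over the list alone, -0.92, adjusted p 0.000252, or 0.342). By pair they were not lower in STAT6 knockout (0.002, 0.235 and 0.241 in that order). The dendritic cell lists fell most on the arrays labelled STAT4 knockout (-2.26 and -2.05), whose high-fat array lies near marrow. In wild-type and HDC knockout spleen these lists and the interferon list were all lower, so the interferon shift is not set apart from one in cell types. For the type I interferon list, the difference between tissues had an adjusted p of 2.02e-05 (0.504 with an estimated correlation). Targets of interferon-gamma and IL-12 acting through STAT4 had 0 calls over all genes in both tissues together, and 1 higher and 9 lower over the list alone (median -0.88, adjusted p 7.17e-07, or 0.288 with an estimated correlation). Lower were Cxcl9 (-2.04, SE 0.39) and Iigp1 (-1.71, SE 0.33) in 8 of 8 pairs and Gbp3 (-1.56, SE 0.35) in 7 of 8. Nos2 was at 1.38 in 7 of 8.

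Early B cell genes were lower in marrow on the high-fat diet by camera at the preset correlation, though not by fry. The pro-B and pre-B cell list had 0 of 11 genes called over all genes and 9 lower over the list alone (median -2.60, adjusted p 9.25e-11, or 0.433 with an estimated correlation). Relative to all features, Rag1 was at -3.15 (SE 0.83), Vpreb3 at -3.05 (SE 0.84), Akap12 at -2.96 (SE 0.76) and Il7r at -2.59 (SE 0.80), each in 4 of 4 pairs. The list's mean level was 0.47 on control and -0.12 on high-fat diet in wild-type marrow, 0.35 and -0.50 in STAT6 knockout marrow, 3.91 and -1.60 in HDC knockout marrow, and 1.70 and -0.54 on the marrow arrays labelled STAT4 knockout, so the control array of HDC knockout marrow weighs most. That array also had the lowest Itgam signal of the marrow arrays (4.597, against 5.241 to 5.896 on the others). A lower CD11b signal is thus not set apart from its high early B cell level. With only the wild-type and STAT6 knockout arrays the adjusted p of the pro-B and pre-B cell list was 4.92e-07. Mature B cell genes followed in marrow (0 called, 6 lower over the list alone, median -1.40, adjusted p 6.07e-09, or 0.433 with an estimated correlation), with Cd72 at -3.11 in 4 of 4 pairs. The drop was not particular to B cells. With 0 called, and 0 over the list alone, other lists were lower in marrow too: megakaryocyte and platelet (median -1.15, adjusted p 9.53e-06, or 0.448 with an estimated correlation), plasma cell (-0.98, adjusted p 6.89e-05, or 0.433), conventional dendritic cell (-0.82, adjusted p 4.02e-05, or 0.433), plasmacytoid dendritic cell (-0.96, adjusted p 0.00308, or 0.448), erythroid (-0.74, adjusted p 0.000401, or 0.448) and T cell (-0.69, adjusted p 0.00115, or 0.448). HDC knockout weighs most in these as well. Without it the mean difference over pairs went from -0.976 to -0.302 for megakaryocyte and platelet (0.238 in the STAT6 knockout pair) and from -0.928 to -0.679 for plasma cell. It went from -0.833 to -0.563 for conventional and from -0.835 to -0.346 for plasmacytoid dendritic cell. For erythroid it went from -0.659 to -0.271 and for T cell from -0.706 to -0.385. By pair the B cell level differed in marrow by -3.20 in HDC knockout, -1.73 on the arrays labelled STAT4 knockout, -0.65 in wild type and -0.40 in STAT6 knockout, a mean of -1.49 that became -0.92 without HDC knockout. In spleen the B cell list was lower with all arrays (median -1.04, adjusted p 0.000109, or 0.382 with an estimated correlation) and higher with only the wild-type and STAT6 knockout arrays (adjusted p 0.00331). By pair it differed there by -3.01 on the arrays labelled STAT4 knockout, whose high-fat array lies near marrow, -0.81 in HDC knockout, -0.06 in wild type and 0.65 in STAT6 knockout, so each direction rests mostly on 1 pair.

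Cholesterol synthesis genes were higher in marrow on the high-fat diet by camera at the preset correlation, though not by fry. Of the list, 23 of 24 had a positive change, 0 were called over all genes and 1, Insig1, over the list alone (median 0.40 relative to all features, adjusted p 1.45e-05, or 0.448 with an estimated correlation, 0.00782 with only the wild-type and STAT6 knockout arrays). By pair the list's level differed by 1.48 in HDC knockout, 0.37 in STAT6 knockout, 0.15 in wild type and 0.07 on the arrays labelled STAT4 knockout, a mean of 0.52 that became 0.19 without HDC knockout. Nsdhl was at 1.07, Fdft1 at 1.16 and Srebf2 at 0.88, each in 4 of 4 pairs. In spleen the cholesterol synthesis list was at -0.09 (adjusted p 0.725), and the difference between tissues had an adjusted p of 4.07e-07 (0.457 with an estimated correlation). The natural killer cell list was at -1.37 in spleen (adjusted p 2.02e-10, or 0.333 with an estimated correlation) and -1.19 in marrow (adjusted p 9.53e-06, or 0.448 with an estimated correlation), but neither held with only the wild-type and STAT6 knockout arrays (0.661 and 0.766). The cell cycle list in spleen was at 0.64 with all arrays (25 of 25 positive, adjusted p 5.7e-07, or 0.435 with an estimated correlation) and lower with only those arrays (adjusted p 0.00338). The inflammatory list over both tissues had a positive median (0.16 before the shift of all features is taken off) and mean (0.15), while its test pointed lower (adjusted p 0.446). The diet changes of spleen and marrow correlated across features at r = 0.54.

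Single pairs of arrays show how unevenly the diets differed. Wild-type spleen had 1369 genes above background on both arrays and at least 2-fold apart between the diets (991 higher, 378 lower), wild-type marrow 1006, STAT6 knockout spleen 1293 and STAT6 knockout marrow 852. The pairs labelled STAT4 knockout had 6643 in spleen and 3246 in marrow, and HDC knockout 5304 and 6698, so the pairs with a difference in sex-linked signal were also those furthest apart. In wild-type spleen the 2 widest gaps in each direction on high-fat against control diet were 2610037D02Rik (3.42), Mug1 (2.75), Skint8 (-3.42) and the complement gene Cfb (-3.29). In wild-type marrow the 2 in each direction were R3hdm4 (5.30), Sephs2 (4.98), Olfr686 (-2.77) and Mnd1 (-2.47). These are values of 1 array against 1 array without a test.

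**Figure D3:**
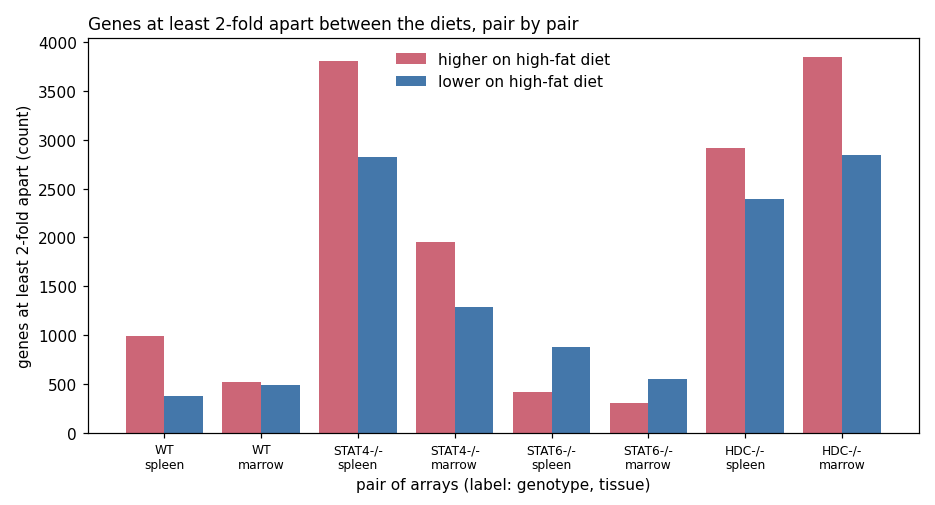
Number of genes at least 2-fold higher or lower on the high-fat than on the control-diet array, for each of the 8 pairs (bars, count of genes; 1 array per diet in each pair). Wild-type and STAT6 knockout pairs have 852 to 1369 such genes in all, the other 4 pairs 3246 to 6698.

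What did all 3 knockouts share against wild type? Oas1a, an interferon-induced antiviral gene, was not above background on any wild-type array and was at least 1047-fold higher on the arrays labelled STAT4 knockout, at least 1025-fold higher in STAT6 knockout and at least 2132-fold higher in HDC knockout (adjusted p 3.58e-05, 1.85e-05 and 5.06e-06, 4 of 4 pairs each). For the arrays labelled STAT4 knockout the median of all features was 0.21, and their other changes are given relative to it. Oas1f, of the same family, was higher by 4.65 on the arrays labelled STAT4 knockout, 5.06 in STAT6 knockout and 6.0 in HDC knockout (SE 0.46, adjusted p 0.00661, 0.00456 and 0.000741, 4 of 4 pairs each), and Ctps2 by 3.15, 3.33 and 2.98 (SE 0.24, adjusted p 0.000514, 0.000567 and 0.000822, 4 of 4 pairs each). Gm10421 was at -5.46, -7.09 and -7.15 (SE 0.32, adjusted p 0.000208, 1.85e-05 and 5.06e-06) and the MHC class I gene H2-Q8 at -4.03, -3.98 and -3.51 (SE 0.40, adjusted p 0.0145, 0.0097 and 0.014), in 4 of 4 pairs each. These 5 genes make up all calls for the arrays labelled STAT4 knockout (3 higher, 2 lower; limma; 2902 at an unadjusted p under 0.05). Since the other knockouts share them, they cannot be assigned to the loss of STAT4.

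On the arrays labelled STAT4 knockout, genes induced by interferon-gamma and by IL-12 through STAT4 were lower as a group. The list had 0 of 23 genes called over all genes and 12 lower over the list alone (median -1.58, adjusted p 7.36e-25, or 0.077 with an estimated correlation, fry 0.0248). Relative to all features, Gbp2 was at -3.32 (SE 0.53), Igtp at -3.31 (SE 0.49), Iigp1 at -3.09 (SE 0.47) and Tap1 at -2.10 (SE 0.31), each in 4 of 4 pairs with adjusted p of 0.131 to 0.135. The type I interferon list had 1 gene higher over all genes, Oas1a, and 1 higher and 3 lower over the list alone (median -1.38, adjusted p 9.53e-19, or 0.177 with an estimated correlation), with Oasl2 at -3.68 and Zbp1 at -2.30. Immune cell lists were lower beside them, each with 0 called, 0 over the list alone and 0.177 with an estimated correlation: T cell (median -1.0, adjusted p 1.35e-09), B cell (-1.11, adjusted p 2.12e-09), MHC class II presentation (-1.02, adjusted p 4.43e-09), conventional dendritic cell (-0.71, adjusted p 1.24e-07) and plasmacytoid dendritic cell (-0.77, adjusted p 4.29e-05). Spleen carries these 5 shifts, most of all its high-fat pair (-3.71 to -2.61 against wild type, and -1.13 to -0.695 on the control diet). In marrow (control, then high-fat diet) the levels differed by 0.452 and 0.005 for T cell, 0.636 and -0.436 for B cell and 0.134 and -0.37 for MHC class II. Conventional dendritic cell differed there by 0.681 and 0.01, and plasmacytoid dendritic cell by 0.031 and 0.007. The natural killer cell list was at -1.63 (0 called, 1 lower over the list alone; adjusted p 3.63e-15, or 0.177 with an estimated correlation), but the natural killer cell level was higher than wild type in both marrow pairs (0.84 and 0.17), and the T cell and B cell lists were low as well on the high-fat spleen array labelled STAT4 knockout (0.05 and 1.51). The 5 calls became 3 without that array and 3 to 6 over all arrays left out in turn, and 47 with the Y-linked signal as a covariate, chosen after seeing the data. Stat4 itself read higher on these arrays than on wild type (0.89 relative to all features, SE 0.62, adjusted p 0.55, 3 of 4 pairs). Whether its probe lies in the deleted part is not known. No part of these shifts can therefore be assigned to the loss of STAT4.

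In STAT6 knockout mice the named calls beyond the shared 5 were Glo1, higher by 1.86 (SE 0.23, adjusted p 0.0397), and Gm4759 (-2.35, SE 0.30, adjusted p 0.0458) and C130026I21Rik (-2.18, SE 0.24, adjusted p 0.017), each in 4 of 4 pairs. The total was 4 higher and 5 lower (limma; 1931 at an unadjusted p under 0.05), and it fell to 3 to 5 when any array of the comparison was left out, for example 3 without STAT6 knockout marrow, control diet. Erythroid genes were higher as a group, with 16 of 16 positive, 0 called over all genes and 11 over the list alone (median 1.69, adjusted p 1.9e-13, or 0.437 with an estimated correlation), with Car1 at 2.32 (SE 0.46), Klf1 at 2.23 (SE 0.57), Rhag at 2.18 (SE 0.60) and Rhd at 2.06 (SE 0.61) in 4 of 4 pairs. In marrow this was not particular to STAT6 knockout. Against wild type (control, then high-fat diet) the erythroid level differed there by 1.44 and 1.67 in STAT6 knockout, 1.14 and 1.37 with the STAT4 label, and 2.51 and 1.12 in HDC knockout. In spleen it differed by 1.89 and 0.99 in STAT6 knockout, 0.742 and -0.465 with the STAT4 label, and -1.225 and 0.181 in HDC knockout. Eosinophil genes had 10 of 10 positive (0 called, 0 over the list alone, median 1.63, adjusted p 4.87e-06, or 0.604 with an estimated correlation), with Epx at 2.65 and Prg3 at 2.04. The interferon-gamma and STAT4 list had 0 called and 13 lower over the list alone (median -0.88, adjusted p 1.65e-12, or 0.411 with an estimated correlation), with Igtp at -2.87 and Gbp2 at -2.77. The natural killer cell list was lower beside it (0 called, 0 over the list alone, median -0.89, adjusted p 3.6e-05, or 0.604 with an estimated correlation). Spleen carries this shift: the natural killer cell level differed from wild type by -2.41 and -1.47 there (control and high-fat diet), and by -0.09 and 0.36 in marrow. The list of IL-4 targets of STAT6 and alternative activation was at -0.14 with an adjusted p of 0.474, and its member Mgl2 at -0.93 (SE 0.28, 4 of 4 pairs, adjusted p 0.478). STAT6 and wild-type arrays lie on different slides, so slide enters each of these values.

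In HDC knockout mice 14 features were higher and 28 lower (limma; 3045 at an unadjusted p under 0.05), and 28 named genes had the same direction in 4 of 4 pairs. Beyond the shared genes, Vps16 (6.16, SE 0.27, adjusted p 5.06e-06), Oas1g (at least 6-fold, adjusted p 0.00827), Gdf3 (3.45, SE 0.50, adjusted p 0.0415), Ubtd1 (3.10, SE 0.46, adjusted p 0.0428), Gchfr (2.02, SE 0.26, adjusted p 0.0232), Glo1 (1.82, SE 0.23, adjusted p 0.0232) and Itpa (1.66, SE 0.23, adjusted p 0.0316) were higher. Rbbp9 (-5.12, SE 0.23, adjusted p 5.06e-06), the endothelial selectin gene Sele (-3.65, SE 0.53, adjusted p 0.0415, above background on 1 of 4 knockout arrays), the cytokine gene Il23a (-3.24, SE 0.50, adjusted p 0.0483), Ccrl2 (-3.09, SE 0.48, adjusted p 0.0484), the itaconate-forming gene Acod1 (-3.04, SE 0.36, adjusted p 0.0177), Arl2bp (-2.99, SE 0.46, adjusted p 0.0484), Mgme1 (-2.75, SE 0.36, adjusted p 0.0257) and Zfp503 (-2.60, SE 0.37, adjusted p 0.0394) were lower. Vps16 and Rbbp9, the 2 genes that set the HDC knockout arrays apart by a gap of 2 log2, lie on the chromosome of Hdc. The other genes named here were not compared with Hdc by chromosome, so whether they lie near Hdc was not tested. On the high-fat HDC knockout arrays, 1.66% of gene windows held at least as high a share of differing genes as the window around Hdc. On the control-diet ones it was 20.99%. For these genes, a difference carried by the region around Hdc is thus not set apart from the loss of HDC. The 42 calls became 16 with the pool as a random block (6 higher, 10 lower), 7 without wild-type marrow, high-fat diet, and 228 without HDC knockout marrow, high-fat diet. Slide and the sex-linked difference enter here too.

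Inflammatory and immediate early genes were lower in HDC knockout mice, most so on the control diet. In the inflammatory cytokine list 0 of 23 genes had a positive change, 2 were called lower over all genes and 16 over the list alone (median -1.65, adjusted p 6.4e-15, or 0.294 with an estimated correlation, fry 0.0572). Among them were Il23a, Ccl4 (-2.55, SE 0.38, adjusted p 0.0473), Ptgs2 (-2.80, SE 0.50, adjusted p 0.0829) and Nlrp3 (-2.73, SE 0.61, adjusted p 0.162), each in 4 of 4 pairs. The immediate early and heat shock list had 0 of 19 positive, 0 called and 12 lower over the list alone (median -1.18, adjusted p 3.42e-11, or 0.64 with an estimated correlation), with Atf3 at -3.17, Zfp36 at -1.36, Dusp2 at -1.26 and Egr1 at -1.07. Its level differed from wild type by -2.27 and -1.48 on the control diet (spleen and marrow) and by -0.55 and -0.35 on the high-fat diet. The inflammatory list was lowest on the control-diet arrays of HDC knockout, 1.91 in spleen and 1.65 in marrow, and stood at 2.93 and 3.24 on their high-fat arrays, where wild-type arrays read 3.58 to 5.17. Those control-diet arrays are also the HDC knockout arrays with low Y-linked and high Xist signal. The sex-linked difference is thus not set apart from the drop, though both lists were lower than wild type on the high-fat arrays too. On those control-diet arrays Itgam was also the lowest of its tissue, on each of its probes. Its brightest probe read 2.996 in spleen (3.637 to 5.891 on the others) and 4.597 in marrow (5.241 to 5.896). A lower CD11b signal is thus not set apart from the drop there. On the high-fat HDC knockout arrays that probe read 4.825 and 5.598 (3.874 and 5.779 in wild type). On the control-diet HDC knockout spleen array the neutrophil lists were also the lowest of all spleen arrays (mature 6.11, secondary granule 5.52, primary granule 3.91; wild type 7.5, 7.11 and 5.54). Over all 4 pairs the mature neutrophil list, which shares Il1b with the inflammatory one, had 0 called and 2 lower over the list alone (median -0.35, adjusted p 0.00629, or 0.727 with an estimated correlation), so a shift in neutrophils is not set apart from this. Red pulp macrophage genes were higher (19 of 20 positive, 0 called, 0 over the list alone, median 1.19, adjusted p 4.23e-07, or 0.64 with an estimated correlation), with Mertk, Hpgd (1.98) and C1qa (1.53) in 4 of 4 pairs. Their level was 3.70 on the HDC knockout marrow array, control diet, and 0.65 to 2.01 on the other marrow arrays. The histamine list showed no shift (6 genes, median 0.03, adjusted p 0.863), and Hnmt, which breaks histamine down, was at -0.71 (SE 0.30, 4 of 4 pairs, adjusted p 0.444).

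**Figure D4:**
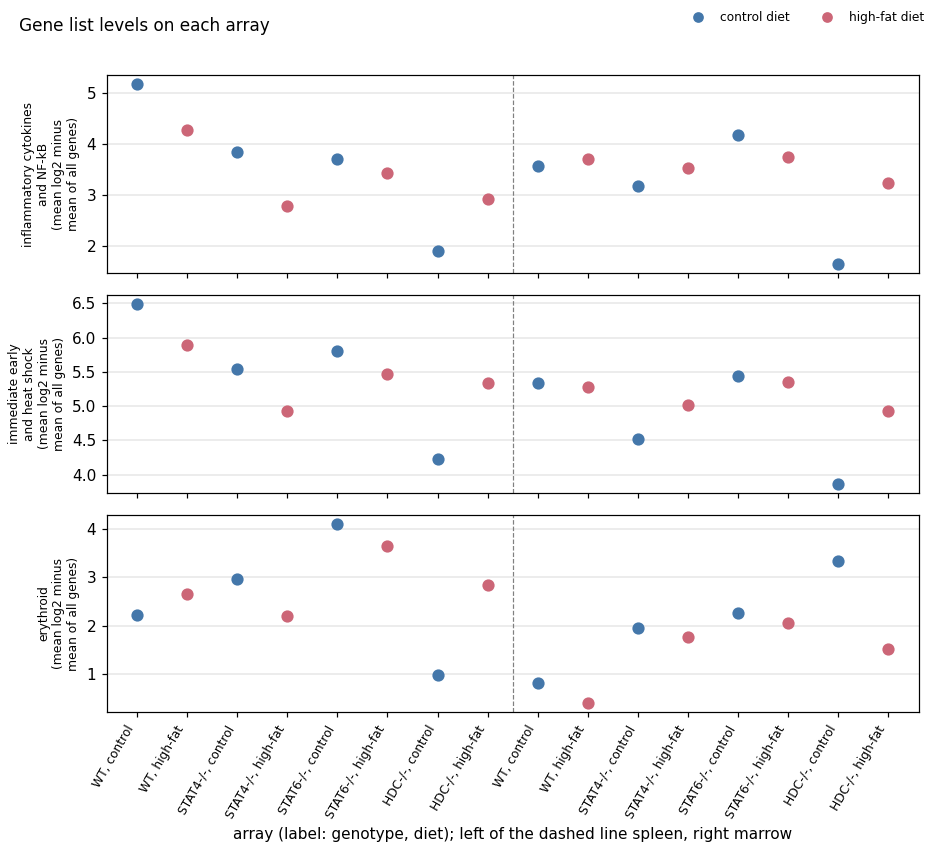
Mean level of inflammatory, immediate early and erythroid genes on each of the 16 arrays (log2, minus the mean of all tested features; 1 point per array). The inflammatory list is lowest on the control-diet HDC knockout arrays (1.91 in spleen, 1.65 in marrow), and the erythroid list reads 4.11 and 3.65 on STAT6 knockout spleen arrays against 2.22 and 2.66 on wild-type spleen arrays.

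Do the knockout changes differ between spleen and marrow? Within a tissue, the arrays labelled STAT4 knockout had 2 features higher and 1 lower in spleen and in marrow alike (median of all features 0.51 and -0.12), STAT6 knockout 3 and 1 in spleen (0.30) and 18 and 886 in marrow (-0.18), and HDC knockout 6 and 2 in spleen (0.33) and 65 and 3218 in marrow (-0.44). The test of the difference itself gave 0 features for the arrays labelled STAT4 knockout (limma; 5436 at an unadjusted p under 0.05), 2091 for STAT6 knockout and 4704 for HDC knockout. Of these, 2085 and 4698 lay toward less signal in knockout marrow, whose 4 arrays form the dim slide. The 6 within-tissue comparisons together had 2.28% of 4205 calls higher. After quantile normalization it was 16% of 437 (70 higher, 367 lower) and after normexp with quantile normalization 50% of 30. The 2091 and 4704 differences became 0 under both. Leaving out wild-type marrow, control diet, brought the 4205 to 21. The correlation between spleen and marrow changes was -0.16 for the arrays labelled STAT4 knockout, -0.19 for STAT6 and -0.23 for HDC, and the last 2 turned to 0.06 and 0.07 after quantile normalization, so neither the marrow counts nor these signs stand apart from the scaling.

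Does the diet act differently by genotype? Against wild type, 0 features passed for the arrays labelled STAT4 knockout (limma; 1462 at an unadjusted p under 0.05; smallest adjusted p 0.0737) and 0 for STAT6 knockout (1314; median of all features -0.21; smallest adjusted p 0.96). For HDC knockout 2 passed of 28469 (3498 at an unadjusted p under 0.05), and both are on the Y chromosome: Eif2s3y (11.15, SE 0.58, adjusted p 0.0034) and Ddx3y (9.87, SE 0.67, adjusted p 0.0115), each higher on the high-fat array in 2 of 2 HDC knockout pairs. They give the sex-linked difference described above, not a response to fat. The 2 calls became 0 without HDC knockout marrow, high-fat diet, and 111 with a trended robust prior. On simulated data 0% of changes of 3 log2 were recovered by this test, so its empty results say little.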

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

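The tests of dim arrays, of the diet itself, of the STAT4 allele, of a swap and of the slide were chosen only after the results they address were seen; the tests of female mice, of STAT6 knockout RNA and of the wild-type colony were written before their values were computed.

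Control-diet arrays labelled STAT4 and HDC knockout had low Y-linked and high Xist signal. Female mice in those pools may explain this, as both signals differ in the direction that female RNA would give. Genes that escape X inactivation differed between high-fat and control arrays by -0.135 (SD 0.27, n = 4 pairs) in those genotypes. Elsewhere they differed by 0.004 (SD 0.28, n = 4 pairs). The gap was -0.14, with an exact two-sided permutation p of 0.543. It is smaller than the SD of either set of pairs, so this test cannot tell and does not count against female mice. Dimness alone does not account for the pattern, since Xist was higher on the control-diet array in 4 of those 4 pairs. High Xist is part of the pattern itself, so this is not a separate test. Median signal (control, then high-fat diet) was 117.6 and 112.8 in spleen labelled STAT4 knockout and 170.2 and 158.8 in HDC knockout spleen. In marrow it was 94.55 and 168.2 with the STAT4 label and 101.1 and 85.92 in HDC knockout. The diet itself is excluded, as the Y-linked genes differed by 0.16 between control and high-fat arrays of wild-type and STAT6 knockout mice.

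Stat4 was not low on any array labelled STAT4 knockout, and Stat6 was low on the control-diet ones, which might hold STAT6 knockout RNA. On those arrays 17.03% of all gene windows held at least as high a share of differing genes as the window around Stat6, which cannot tell. That only the high-fat arrays hold the STAT4 allele also stays open: 6.998% of windows differed at least as much as the one around Stat4, and the first criterion set for this test (top 5% in both diets or in neither counts against it) would have excluded it. That criterion was withdrawn after the value was seen, because such windows reached the top 5% around Hdc on the high-fat HDC knockout arrays (1.66%) but not on the control-diet ones (20.99%), nor around Stat6 on the arrays labelled STAT6 knockout (46.5% and 18.2%), so missing it excludes little. A swap of the high-fat arrays with those labelled STAT6 knockout is not excluded. On the brightest probe their Stat6 lay at least 0.897 above the highest array labelled STAT6 knockout (SD 0.21, n = 4). The other probes gave 1.04 (SD 0.49) and 0.18 (SD 0.46), the last gap smaller than its SD. The criterion was set after these values were seen and takes the STAT6 labels as true. A swap of the control-diet arrays stays open as well. Stat6 was below every wild-type array on 4 of 4 arrays labelled STAT6 knockout, first read as excluding a swap. However, 1 of the 3 probes gave 3 of 4, and 3 or 4 of the 4 HDC knockout arrays also lay below on each probe.

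Oas1a and other genes differed between wild type and all 3 knockouts, which could come from a different colony or strain of the wild-type pools. This stays open: 4 genes set all wild-type arrays apart by a gap of 2 log2 (0 for the arrays labelled STAT4 knockout, 0 for STAT6 knockout, 2 for HDC knockout), but all 4 are among the shared calls that raised the question. The count was first read as support, and was set aside after it was seen because it only repeats those calls. The slide is excluded: within a slide Oas1a differed by a measured 10.05 or more, and by at least 9.57 where the wild-type value is raised to the lowest signal above background.

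Among 82 groups of up to 8 values tested for a single outlying value by a Dixon test (critical ratio 0.526 for 8 values), 16 had one. The groups share the same arrays, and most of the 16 fall on HDC knockout marrow, control diet. They are therefore not independent, and the number that chance would give is not known. Stat4 was 3.35 on the high-fat spleen array and 2.60 on the high-fat marrow array labelled STAT4 knockout. On that spleen array the T cell list was 0.049, the B cell list 1.51 and the MHC class II list 2.75. The mature neutrophil list was 6.11 in HDC knockout spleen, control diet. In HDC knockout marrow, control diet, the lists read 3.70 for red pulp macrophage, 3.06 for plasmacytoid dendritic cell, 1.76 for natural killer cell, 3.02 for megakaryocyte and platelet, 2.38 for basophil and mast cell, 0.51 for stromal and endothelial cell, 5.55 for type I interferon, 3.32 for MHC class II, 1.65 for inflammatory cytokines and 3.08 for fatty acid oxidation. Changes that differed between groups numbered 2091 genes for STAT6 knockout in spleen against marrow, 4704 for HDC knockout in spleen against marrow, and 2 for diet in HDC knockout against wild type.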

How the results depend on the processing

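The settings marked as added were chosen only after the results were seen. Of 365 alternatives run on the main comparisons, 269 kept the result, 90 moved it and 6 reversed it. Kept means a count within 1.5 times, a correlation close to the main one, or the same call for a targeted gene. A count of 0 that stayed at 0, as for diet, is among those kept. The cause was not tested for any array left out. Diet counts stayed at 0 throughout. Not run: slide as a fixed term for tissue, STAT6 or HDC, which slides do not allow, and pool as a block for diet by genotype. Each pool is 1 combination of genotype and diet, so such a block cannot be told from that term. The pool correlation was 0.233 and the slide correlation -0.008.

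Spleen against marrow (9130 genes): 4991 at 2-fold, 5393 without wild type (4055 higher, 1338 lower), 4811 without STAT6 knockout, 2897 without the control-diet arrays labelled STAT4 knockout (added; 1768 higher, 1129 lower), and 5731 to 10640 with 1 array left out. Arrays labelled STAT4 knockout against wild type (5): normexp 3, additive model 25, slide block 17, the same model without block 18 (added), Y-linked covariate 47 (added; 12 higher, 35 lower), without the 2 arrays nearer the other tissue 3 (added), and 3 to 6 with 1 array left out. STAT6 knockout (9): additive model 14, without the control-diet arrays labelled STAT4 knockout 3 (added), and 3 to 5 with 1 array left out. HDC knockout (42): trended robust prior 65, pool block 16, Y-linked covariate 24 (added), without the 2 arrays nearer the other tissue 19 (added), without the control-diet arrays labelled STAT4 knockout 13 (added), and 7 to 228 with 1 array left out. Diet by STAT4 label (0): stricter filter 3, trended robust prior 4, additive model 3, slide block 3. Diet by HDC (2): quantile 1, normexp 0, stricter filter 8, trended robust prior 111, additive model 9, slide block 10, and 0 to 2 with 1 array left out. Each knockout within a tissue (4205): each tissue on its own 2491, trended robust prior 2216, quantile 437, normexp 30, and 21 to 5994 with 1 array left out.

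List shifts (150) were 0 with an estimated correlation and 22 by fry. With only wild-type and STAT6 knockout arrays (added) the direction turned on the high-fat diet in spleen for secondary granule (adjusted p 0.0124), red pulp macrophage (0.0303), B cell (0.00331) and cell cycle (0.00338), in marrow for red pulp macrophage (0.000673), over both tissues for red pulp macrophage (0.000169), and for the cell cycle difference between tissues (0.00333). The Y-linked covariate (added) turned red pulp macrophage in spleen (0.000264) and over both tissues (0.00426). Over the other settings the highest adjusted p of these lists came from fry, 0.455 to 0.9.

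The spleen-to-marrow correlation of changes turned for STAT6 knockout (-0.19) to 0.0646 with quantile, 0.275 with normexp and 0.409 for genes above the median signal, and for HDC knockout (-0.23) to 0.0719, 0.342 and 0.401. For the arrays labelled STAT4 knockout (-0.16) it was -0.0171 with normexp and -0.037 above the median; for diet (0.54) it was 0.655 above the median.

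Single diet pairs, in genes at least 2-fold apart, then with normexp, without filter and at 3-fold, were as follows. Wild-type spleen had 1369, 460, 5848, 261. Wild-type marrow had 1006, 444, 2256, 182. STAT4 label marrow had 3246, 1767, 6160, 820. STAT6 spleen had 1293, 554, 2417, 286. STAT6 marrow had 852, 277, 4164, 184. HDC marrow had 6698, 4298, 11571, 2936. STAT4 label spleen (6643) gave 4391 with normexp and 2605 at 3-fold, and HDC spleen (5304) 2426 at 3-fold.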

Other observations

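No test in this part was chosen after the result was seen, apart from the settings named as chosen after seeing the data.

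Eosinophil genes varied more between groups than the report's comparisons bring out. Their mean level in marrow was 4.98 and 4.54 in STAT6 knockout (control and high-fat diet) and 5.38 on the control-diet array labelled STAT4 knockout, against 2.57 and 2.55 in wild type and 3.29 and 2.81 in HDC knockout. In spleen the control-diet arrays read 3.95 (labelled STAT4 knockout), 3.78 (STAT6 knockout), 2.46 (wild type) and 0.74 (HDC knockout), and the high-fat arrays 1.38, 2.40, 2.13 and 2.54 in the same order. High-fat marrow labelled STAT4 knockout read 2.97, so with that label the high values lie on the control diet alone. Of the 10 genes, all 10 were higher in STAT6 knockout (adjusted p 4.87e-06; 0.604 with an estimated correlation) and all 10 on the arrays labelled STAT4 knockout (adjusted p 0.021; 0.562). All 10 were well above background on every spleen and marrow array, and 1 belongs to another list.

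Glo1 was higher in STAT6 knockout (1.86, SE 0.23, adjusted p 0.0397) and in HDC knockout (1.82, SE 0.23, adjusted p 0.0232), in 4 of 4 pairs each. Fatty acid synthesis genes were higher in HDC knockout, 14 of 16 positive (0 called, 0 over the list alone; median 0.44, adjusted p 0.000592; 0.221 with an estimated correlation; fry 0.0514), with Thrsp at 1.09, Fads1 at 0.73, Fads2 at 0.68 and Scd2 at 0.62. Marrow carries this shift of the fatty acid synthesis list: against wild type its level differed by 0.85 and 0.75 there (control and high-fat diet), and by -0.07 and 0.26 in spleen. Stem and progenitor genes in marrow were lower on the high-fat diet by camera at the preset correlation, though not by fry (median -0.84 relative to all features, adjusted p 1.45e-05, or 0.433 with an estimated correlation). Gata1 was at -1.77 and Adgrg1 at -1.33. With only wild-type and STAT6 knockout arrays the adjusted p of that list was 0.124.

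Arrays were also split in other ways than by the labels, to see whether chance could give the counts. For spleen against marrow chance is excluded: 1 of 100 splits, the real one, reached 9130 genes, and the highest other gave 4747. For the arrays labelled STAT4 knockout 1 of 34 splits, the real one, reached 5, and the highest other gave 0. Many of these splits set unequal numbers of spleen and marrow arrays, or of the 2 diets, against each other. They are thus unlike the real split, and too few keep the tissue-and-diet pairs for this share to exclude chance. For diet the real count is 0, which every split reaches, so the splits test nothing: 32 of 32 in spleen (highest other 40), 32 of 32 in marrow (highest other 3) and 100 of 100 over both (highest other 645). For STAT6 knockout (2 of 34 splits; 9 genes, highest other 2091) and HDC knockout (2 of 34; 42, highest other 4704) the share of splits alone does not exclude chance. The only other split to reach the count groups wild-type spleen with knockout marrow, which is the knockout by tissue comparison and points to a structure of the samples, tissue and slide. The remaining splits gave at most 2 genes for STAT6 knockout and 4 for HDC knockout.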
